A study of Fundulus heteroclitus with 4 samples.

How the data were processed

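Small RNA of Atlantic killifish (Fundulus heteroclitus) embryos was measured in 4 libraries, 1 for each combination of population and stage. Per the labels' protocols, gametes of adults from Scorton Creek (SC) and New Bedford Harbor (NBH) were fertilised in vitro, the F1 embryos were kept in sea water at 22 °C, and total RNA with an integrity number above 9.8 was used. Libraries were made with a small RNA expression kit and read on a SOLiD V3 instrument, per the labels' protocols. The pooled sample combined embryos of 1 to 15 days post-fertilisation (dpf), and the other sample held embryos of 12 dpf, so the days of the pooled sample include 12 dpf.

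The authors deposited, for each library, raw read counts per mature miRNA, with no normalisation, together with counts of reads identical to the listed sequence and of reads matching a single reference entry, per the file headers. The names come from zebrafish, pufferfish and medaka miRNAs, per the file headers. The aligner, the mismatches allowed, the program version and the reference release are not given in the sources used here. A list of 197 hairpin positions without names was used to count clusters; its genome build is not given in the sources used here.

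The 4 tables were joined by sequence into 217 entries, of which 199 were listed in every library. miR-27c and miR-92a were joined by name: the pooled SC table gave miR-27c the sequence of miR-218b, and gave miR-92a with 1 base fewer. An entry a table did not list was set to 0 counts; the highest count of such an entry elsewhere was 83 (miR-22b, which has no ratio in comparisons with SC at 12 dpf). Entries with the same name carry their species or the letters A and B.

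Entries with at least 10 counts in at least 2 libraries were kept, which left 192. Library sizes were scaled by TMM (edgeR 4.0.16, R 4.3.3). The log2 ratio of 2 libraries used a pseudocount of 0.5 scaled to library size, and its 95% interval is the exact conditional binomial (Clopper-Pearson) interval of the 2 counts. Reads are not independent molecules, so these intervals cover counting error only. A miRNA was called higher or lower at 2-fold or more with an interval that excluded equality. With 1 library per group no difference has a replicate check, and no p-value was computed within a pair of libraries.

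An auxiliary additive model of population and stage over all 4 libraries was fitted with the quasi-likelihood test of edgeR, at a Benjamini-Hochberg adjusted p of 0.05. It has 1 residual degree of freedom, and its spread is the departure of the population difference at one stage from that at the other. DESeq2 1.42.0 was the alternative. Correlations across miRNAs carry no p, since miRNAs are not independent replicates. Of 29 miRNA lists chosen before the data were examined, 25 had 2 or more measured members. The median ratio of each was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The random lists drew their members independently of family. Lists of related miRNAs, whose ratios can move together, can therefore reach extreme percentiles more easily. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

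The miRNAs named are members of those lists, the 10 most abundant, the 5 highest and 5 lowest ratios of each comparison among miRNAs with at least 100 counts in 1 of its libraries, and up to 10 in each direction that differed at least 2-fold the same way in both pairs of libraries. miRNAs named for differing in opposite directions, or for being low in a single library, were chosen after their values were seen.

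The ratio rule was tested on simulated data of 192 miRNAs with counting error alone: it recovered 98.8% of 40 miRNAs changed 4-fold, made 0.35 false calls per draw on average, and its intervals held the true ratio in 95.4% of cases. For the additive population fit, simulated data of 192 miRNAs with a dispersion of 0.02 gave back 96.5% of 4-fold changes. At a dispersion of 0.43, near the fitted common dispersion of 0.431, it gave back 0% of 4-fold and 50.5% of 16-fold changes. Alternatives were total counts or DESeq2 size factors for scaling, no count filter, a filter of 100 counts, a pseudocount of 5, identical reads alone, sums by family, scaling without the 5 most abundant miRNAs, and each library left out of the additive fits.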

Results

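Mature miRNAs were counted in embryos of 2 populations of Atlantic killifish, SC and NBH, as a pool of 1 to 15 dpf and at 12 dpf, with 1 library for each. The deposited read counts came to 1601093 in pooled SC, 1780462 in pooled NBH, 2343143 in SC at 12 dpf and 2299850 in NBH at 12 dpf. At most 210 entries were listed per library. Because no group had a second library, each ratio below has no replicate check, and its interval covers counting error only.

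The most abundant miRNA by the mean of the 4 libraries was miR-204, a miRNA of the eye, at 81813 normalised counts per 1000000 (CPM), although in SC at 12 dpf miR-203a stood above it (66359 against 59977 CPM). By mean it was followed by miR-130c at 64302 CPM and miR-203a, a miRNA of skin, at 51711 CPM. miR-199, miR-19b, miR-181a, miR-103, miR-125b, miR-99 and miR-301c made up the rest of the 10 most abundant, at 35216 to 30228 CPM. These 10 held between 39.9% of the counts in SC at 12 dpf and 46.1% in pooled NBH. Reads identical to the listed sequence made up 56.2% to 59.9% of the counts. Among the 168 miRNAs with at least 100 counts in a library, 55 had fewer than 10% identical reads and 21 fewer than 1%. Their names rest on reads that differ from the listed sequence, by length or by mismatches, which the counts do not separate.

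The first comparison set NBH against SC in the pooled embryos. miR-21 was lower in NBH by the widest margin, with 30 counts against 2602 and a log2 ratio of -6.36 (interval -6.96 to -5.87). miR-210, a miRNA induced by hypoxia, followed at -4.32 (-4.50 to -4.15), with miR-93 at -4.26, miR-460 (dre-5p) at -3.14 and the neural miR-124 at -2.96. In identical reads miR-21 no longer had the widest margin of these, at -4.19 (2 reads against 48, interval -7.57 to -2.56). There miR-210 stood at -5.24, miR-93 at -4.89, miR-460 (dre-5p) at -4.86 and miR-124 at -2.18. The highest ratios belonged to miR-181a at 2.45 (2.42 to 2.47), miR-30c (dre) (interval 1.96 to 2.04), miR-454b at 1.94 (1 identical read in SC and 0 in NBH), miR-30d at 1.83 and miR-217 at 1.68. All 5 entries of the miR-30 family were called higher, with a median of 1.39 at percentile 99.9 of the random lists. With total counts 3 of the 5 were. In both pooled libraries miR-30e, miR-30c (dre) and miR-30c (tni,fru) had fewer than 10% identical reads, the last of these 0. Their reads cannot be assigned to those names with certainty, so the entries may not be separate observations. In identical reads miR-30c (dre) fell to 1.39 (interval 1.10 to 1.69) and miR-30d to 1.28. Of the 3 members of the miR-181 family, 2 were called higher (median 1.47, percentile 98.9). Identical reads gave a ratio for 2 of the 3, 1 higher and 1 lower (median -0.50). In them miR-181a was higher, with 63295 reads in NBH and 9880 in SC. miR-181b was lower, with 18 and 270 reads, only 0.0469% and 1.00% of its reads.

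Members of the miR-17-92 clusters, which are tied to cell proliferation, moved apart in the pooled embryos. Of 14, 2 were called higher (miR-19b at 1.22 and miR-19c at 1.18), 6 lower, among them miR-20b at -2.92 and miR-20a at -1.71, and 6 neither. Their median was -0.71 (percentile 0.100), while the ratio of their summed counts was 0.38, of opposite sign. The epithelial list had a median of 0.67 (percentile 98.9), with 2 of 9 members called higher, 2 lower and 5 neither. In all, 19 miRNAs were called higher and 40 lower in NBH. Scaling by total counts gave 11 higher and 47 lower, and shifted the median of all miRNAs by -0.21.

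At 12 dpf the ratios of NBH to SC were led by other miRNAs. miR-727 had 123 counts against 1 (6.48, interval 4.58 to 12.40), of which 1 and 0 were identical to the listed sequence, too few for a direction. The endothelial miR-126 stood at 6.14 (5.96 to 6.34), miR-462 at 5.76, miR-124 at 5.68 and the erythroid miR-144 at 4.98. In SC miR-462 had 6 counts and miR-144 had 9. The lowest ratios were those of miR-27c at -6.64 (-7.61 to -5.92), miR-27b at -5.55, miR-458 (dre) at -4.32, miR-725 at -2.85 and miR-129 at -2.35. Only 3.23% of the reads of miR-126 and 0.0661% of those of miR-725 were identical to the listed sequence, and identical reads alone had intervals that included equality for miR-458 (dre) (5 in each library), miR-725 (3 in NBH and 2 in SC) and miR-129 (11 in NBH and 12 in SC).

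The library of SC at 12 dpf, which enters each of these ratios, stood apart: across miRNAs its Spearman rho was 0.881 with pooled SC, 0.892 with pooled NBH and 0.922 with NBH at 12 dpf, below the 0.936 to 0.952 found among those, and it held 13 of the 23 miRNAs found low in a single library, miR-126 with 230 counts among them. By list, all 3 miR-181 members were called higher in NBH at 12 dpf (median 1.30, percentile 97.6). Identical reads at 12 dpf were few for miR-181b (2 in SC and 11 in NBH) and miR-181c (1 and 0). For miR-181a they were 41595 and 95551. Both endothelial entries, miR-126 and miR-126b, were called higher (median 3.77, percentile 99.1). The miR-30 family had 1 of 5 members called higher (median 0.61, percentile 90.4). The miR-17-92 clusters had 7 of 14 members called higher and 0 lower (median 0.79, percentile 98.8), and the miRNAs encoded between Hox genes 4 of 8 higher and 0 lower (median 0.91, above the 0.86 that bounded 97.5% of the random lists). For the liver and gut, miR-122 was higher (2.53) while miR-192 (-1.54) and miR-194 (-1.07) were lower. In all, 46 of 191 miRNAs were called higher and 26 lower. Total counts shifted the median by -0.12, as did DESeq2 size factors.

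The 2 population comparisons share no library. miR-181a, miR-181c, miR-19b, miR-19c and miR-30d were called higher in NBH in both, with 12 dpf ratios of 1.16, 1.47, 1.08, 1.19 and 1.13. Independent lists of these sizes would share 4.58. miR-489 was called lower in both, at -1.89 and -1.86, where independent lists would share 5.31. miR-181c had 0.0124% and miR-489 0% identical reads, and their reads cannot be assigned to those names with certainty; in identical reads alone miR-19c was lower in pooled NBH (-1.13). Calls in opposite directions numbered 21, against 12.0 for independent lists. Across 191 miRNAs the 2 ratios had a Pearson r of -0.166 (interval over resampled families -0.321 to -0.0317) and a Spearman rho of -0.170.

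**Figure D1:**
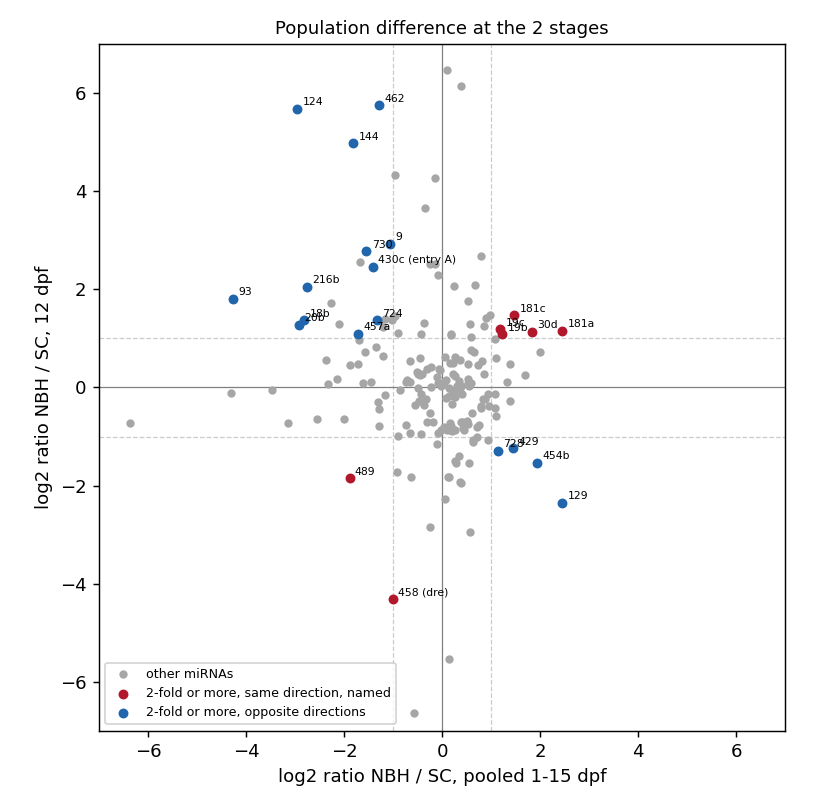
Each point is a miRNA, with the log2 ratio of NBH to SC in pooled embryos on the x axis and at 12 dpf on the y axis, 1 library per population and stage; dashed lines mark 2-fold. Red points are the miRNAs named for differing 2-fold the same way at both stages (miR-458 (dre) had a pooled interval that included equality). Blue points are those with at least 100 counts in a library that were called in opposite directions, and others so called are grey. Across all points r was -0.166.

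In the additive fit of population over both stages, edgeR called 0 miRNAs at an adjusted p of 0.05. Under an unadjusted p of 0.05 were 7, no more than chance would give among the miRNAs tested. All 7 were higher in NBH, but they were miR-19a, miR-19b, miR-19c, miR-19d, miR-181a, miR-181c and miR-30d, most of them relatives. With total counts 3 were higher and 1 lower under that p, and with DESeq2 size factors 5 and 1. The DESeq2 Wald test called 9 higher and 3 lower, among them miR-19b, miR-181c, miR-181a, miR-19a, miR-19c, miR-30d and miR-19d as higher and miR-214, miR-489 and miR-21 as lower. This test used the same 4 libraries and also left 1 residual degree of freedom. miR-21 was at least 8-fold below the median of the other 3 libraries in pooled NBH, with 30 counts, so 1 library weighed on its call. For miR-19b DESeq2 gave a log2 fold change of 1.08 (standard error 0.21) and an adjusted p of 2.75e-05. The quasi-likelihood test of edgeR gave it a like change, 1.15 (standard error 0.27), but an adjusted p of 0.988. Neither p measures a spread between replicate libraries.

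The comparison of 12 dpf with the pool asked which miRNAs differed with stage. In SC, miR-206, a miRNA of skeletal muscle, was higher at 12 dpf (3.24, interval 3.20 to 3.28). Also leading were miR-129 (5.82), miR-454b (4.26), miR-429 (3.37) and miR-728 (3.25, from reads of which 3 and 1 were identical). Of these, miR-129 had 3 counts in the pool. Its identical reads were 12 at 12 dpf and 0 in the pool, and those of miR-454b 19 and 1. The lowest were miR-462 (-6.78), miR-126 (-6.66), miR-144 (-6.15), miR-430c (entry A) (-6.12) and miR-196a (-5.48). At 12 dpf miR-462 had 6 counts, 0 of them identical, miR-144 had 9, 2 of them identical, and miR-430c (entry A) had 13. All 7 entries of miR-430, a family that clears maternal mRNA in fish embryos, were called lower, with a median of -2.88 (percentile 0.0700). The Hox cluster miRNAs had 6 of 8 members lower (median -1.94, percentile 0.110), the miR-17-92 clusters 7 of 14 lower and 1 higher (median -0.97, percentile 0.845), and both endothelial entries were lower (median -4.43, percentile 0.975). These values rest on the same library of SC at 12 dpf as the population ratios of that stage. In all, 51 of 191 miRNAs were called higher and 57 lower, and scaling without the 5 most abundant miRNAs gave 62 and 53, with more calls in the other direction.

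In NBH, miR-206 was again higher at 12 dpf (2.13, interval 2.10 to 2.16). The highest ratios were those of miR-216b (6.35, with 3 counts in the pool), miR-21 (6.04), miR-124 (5.40), miR-210 (5.20) and miR-93 (4.81). In identical reads miR-93 fell to 0.99 (92 reads at 12 dpf and 37 in the pool), while the others of these stayed at 4.82 or above. miR-216b, miR-21, miR-210 and miR-93 were among the miRNAs found low in pooled NBH, which also enters the pooled population ratios. The lowest ratios were those of let-7h (-5.36, with 6 counts at 12 dpf), miR-27c (-4.77), miR-27b (-4.67), miR-430b (entry A) (-2.76) and miR-430c (entry A) (-2.25). Of the 7 miR-430 entries 5 were called lower and 2 neither (median -1.66, percentile 0.0150). The Hox cluster median was -0.46 (percentile 1.41), with 1 of 8 members lower and 7 neither. The miR-17-92 clusters had 5 of 14 members called higher and 2 lower (median 0.41, percentile 96.9), and of the 2 endothelial entries 0 were called (median -0.28, percentile 21.8); the difference of these lists from SC was not tested. In all, 27 miRNAs were called higher and 23 lower. DESeq2 size factors gave 23 higher and 28 lower and shifted the median by -0.11, and total counts gave 32 and 19, so which direction held more calls depended on the scaling.

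The stage ratios of the 2 populations again share no library. Calls higher at 12 dpf in both numbered 11, against 7.21 for independent lists, and calls lower in both 13, against 6.86. Among miRNAs with at least 100 counts in a library, miR-206, miR-454a, miR-216b, miR-301a, miR-301b, miR-190, let-7d, miR-723 and miR-135b were higher in both. Of these 9, identical reads gave the same direction in both populations, with intervals excluding equality, for 4: miR-206, miR-216b, let-7d and miR-135b. The SC ratio of miR-301a turned to -1.95 in them (4 reads at 12 dpf and 12 in the pool), that of miR-190 was at equality, and miR-723, miR-301b and miR-454a had 0 identical reads in 1 library or more. miR-430a, miR-430b and miR-430c (entry A of each), miR-430d, miR-92a, let-7h, miR-200b, miR-499, miR-16b and miR-181b led those lower in both. Identical reads gave the same direction in both for 7 of these 10, but not for miR-181b in NBH. Nor did they for miR-430b and miR-430c (entry A of each), which had 0 identical reads in all libraries. By all reads miR-92a stood at -2.26 in SC and -2.05 in NBH. It was listed with 1 base fewer in pooled SC, so its identical reads there refer to another sequence than at 12 dpf. Across 191 miRNAs r was 0.190 and rho 0.235, and the interval of r over resampled families, -0.00682 to 0.377, included 0. Without the miRNAs extreme in 1 library, an analysis chosen after seeing the data, r was 0.227 and its interval, 0.0364 to 0.406, did not. Intervals over families cover the choice of miRNAs within these libraries, not variation between libraries. They therefore do not show whether the populations share a stage difference. For stage, edgeR called 0 miRNAs in the additive fit, with 11 under an unadjusted p of 0.05, close to the number chance would give. The DESeq2 Wald test called 12 higher and 18 lower. With 1 library left out, edgeR was fitted to stage alone, without the population term, and 1 library stood for 12 dpf: it called 6 miRNAs without SC at 12 dpf and 18 without NBH at 12 dpf, and these counts are not of the same model as the 0.

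**Figure D2:**
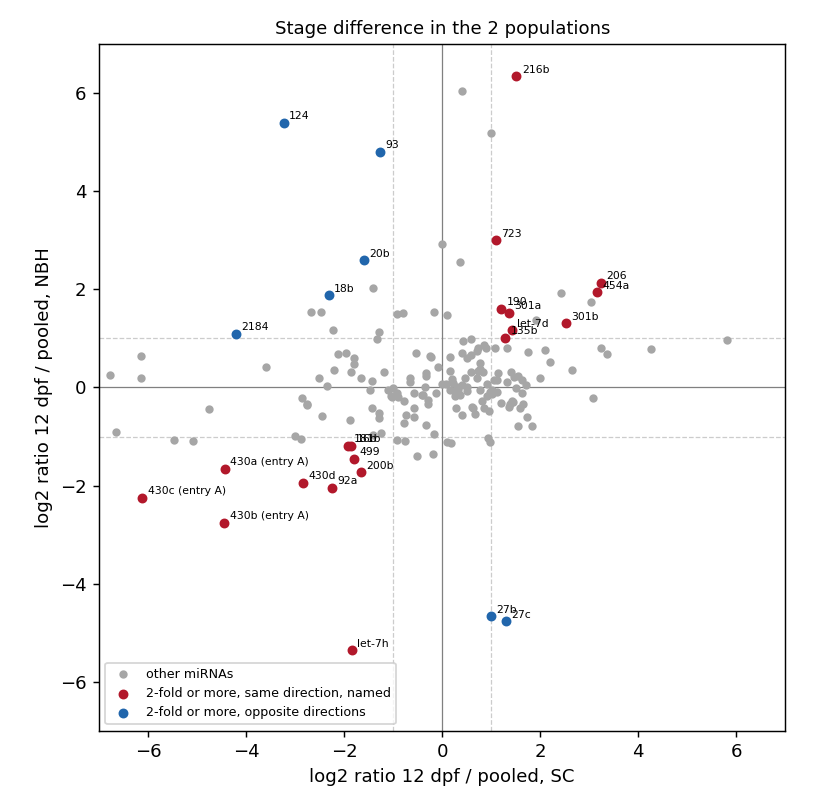
Each point is a miRNA, with the log2 ratio of 12 dpf to pooled embryos in SC on the x axis and in NBH on the y axis, 1 library per population and stage; dashed lines mark 2-fold. Red points are the miRNAs named for differing 2-fold the same way in both populations, the miR-430 entries among them at the lower left. Blue points are those with at least 100 counts in a library that were called in opposite directions, and others so called are grey. Across all points r was 0.190.

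**Figure D3:**
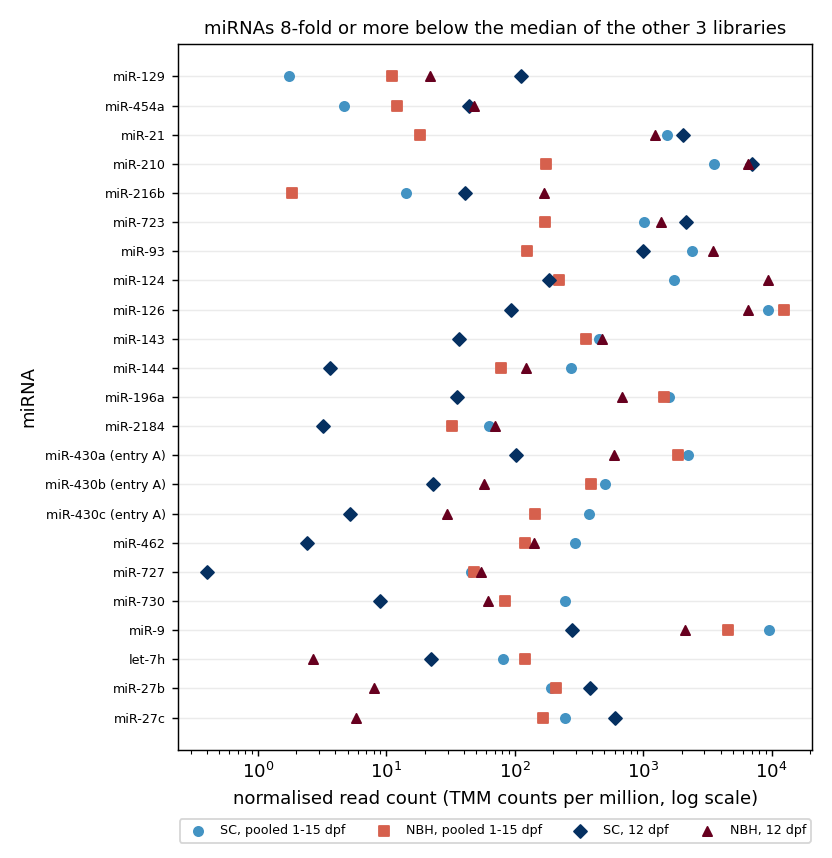
Normalised read count (TMM counts per 1000000, log axis) of the 23 miRNAs that were at least 8-fold below the median of the other 3 libraries in 1 library; each marker is 1 library. Of these, 13 were low in SC at 12 dpf, 5 in pooled NBH, 3 in NBH at 12 dpf and 2 in pooled SC, and some, such as miR-124, were nearly as low in another library.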

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

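All tests in this part were chosen after the results they bear on had been seen. The other scalings and identical reads had been chosen as alternatives before the data were examined, but their use as tests of these patterns came after. The differences listed here were not tested themselves, since each group has 1 library.

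The ratio of NBH to SC went in opposite directions at the 2 stages for 16 miRNAs with at least 100 counts. The 12 dpf ratio exceeded the pooled one, on the log2 scale, by 8.64 for miR-124, 7.06 for miR-462, 6.79 for miR-144, 6.07 for miR-93, 4.81 for miR-216b, 4.32 for miR-730, 4.19 for miR-18b, 4.19 for miR-20b, 3.99 for miR-9, 3.88 for miR-430c (entry A), 2.80 for miR-457a and 2.70 for miR-724. It lay below by -4.80 for miR-129, -3.48 for miR-454b, -2.68 for miR-429 and -2.43 for miR-728. The stage ratio of NBH differed from that of SC, in opposite directions, by 8.64 for miR-124, 6.07 for miR-93, 5.30 for miR-2184, 4.19 for miR-18b, 4.19 for miR-20b, -5.67 for miR-27b and -6.06 for miR-27c. Both kinds of difference are the same contrast of the 4 libraries, so a miRNA in both lists is 1 observation. In identical reads 9 of the 16 still had opposite population ratios with both intervals excluding equality. For miR-93 (-4.89 in pooled embryos and -1.36 at 12 dpf) and miR-9 (0.45 and 2.51) both ratios had the same sign, and for the other 5, miR-129 among them, an interval included equality or a library had no such reads. Of the 7 stage differences 4 stayed opposite, those of miR-93 and miR-27c among them, and for 3 these reads gave no answer. In pooled SC miR-27c was listed with the sequence of miR-218b, so what its identical reads there matched is uncertain. For miR-27b the SC ratio was -1.86 (9 reads at 12 dpf and 24 in the pool), below 0 like the NBH ratio of all reads.

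A first pattern is that 23 miRNAs were at least 8-fold below the median of the other 3 libraries in 1 library, 13 of them in SC at 12 dpf. In the other direction, 6 were at least 8-fold above that median in 1 library. Among both sets were miR-430b and miR-430c (entry A of each), miR-129, miR-124 and miR-216b, which varied in more than 1 library. Library totals differed by at most 1.46-fold, but counts had been scaled for library size before the 23 were picked, so this is no test of depth. For 9 of the 10 with a near-identical entry such entries held at most 0.392% of the missing reads. This argues against reassignment, except for miR-430a, miR-430b and miR-430c (entry A of each). All 7 miR-430 entries were called lower in SC at 12 dpf than in the pool, so an excess within the family could not show. Likewise miR-27b and miR-27c were both low in NBH at 12 dpf, so neither could show an excess from the other. The case of let-7h (813%) stays open because its relatives are far more abundant, and the 13 with no such entry were not tested by this. For the 6 with a partner held to share a primary transcript in other vertebrates, the partners had a median deviation of -0.0897 (SD 0.705), but such pairs had no closer ratios than random pairs in these data, so lower transcription stays open. It stays open too for the other 17. Among these, miR-430a, miR-430b and miR-430c (entry A of each) were low together in SC at 12 dpf (-4.18, -4.08 and -4.72). In NBH they were also lower at 12 dpf than in the pool (-1.66, -2.76 and -2.25), so their fall at 12 dpf was not confined to SC. The latter 2 had 0 identical reads in all libraries, so their reads cannot be assigned to these names with certainty. A difference of these embryos and an effect of library preparation cannot be told apart with 1 library per group.

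A second pattern is that the population differences at the 2 stages were not alike. The mean square of the difference between the 2 stages in the population ratio was 43.2 times that of counting error alone, which argues against counting error but not against other variation between libraries. Without the miRNAs extreme in 1 library r was -0.103 (interval over families -0.287 to 0.0841), so those miRNAs alone do not hide a shared difference. Differences that depend on stage and variation between libraries cannot be told apart with 1 library per group.

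The last pattern is the 5 miRNAs called higher in NBH at both stages. Chance overlap may account for their number, since independent lists would share 4.58. Under the other scalings all 5 stayed above equality at both stages, and 3 were at least 2-fold higher with total counts and 4 with DESeq2 size factors. That all 5 stayed above equality was fixed in advance. Another scaling shifts all ratios of a comparison alike, by at most 0.21 here, and the 5 had been picked at ratios of at least 1.08. It is no test of the scaling. In identical reads 3 stayed above equality at both stages and 2 of them at least 2-fold. miR-30d fell to 0.38 at 12 dpf, miR-19c turned to -1.13 in pooled embryos, and miR-181c had at most 1 identical read per library. For these, an effect of reads that differ from the listed sequence stays open.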

How the results depend on the processing

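The correlation without miRNAs extreme in 1 library and the list medians in identical reads were chosen after seeing the data; all other alternatives were chosen before the data were examined. Counts of called miRNAs stayed within 1.5 times under both scalings, both filters, the pseudocount of 5, identical reads and scaling without the 5 most abundant, except that total counts gave 11 higher in NBH in pooled embryos in place of 19. Sums by family, which leave 112 features, gave 10 higher and 23 lower for NBH against SC in pooled embryos, 22 and 12 at 12 dpf, 18 and 28 for stage in SC, and 14 and 15 for stage in NBH. The DESeq2 Wald test called 12 miRNAs for population and 30 for stage, where edgeR called 0; the cause was not tested. Leaving out each library in turn, with the other factor dropped as well, gave 0 for population and 0 to 18 for stage, with a single library standing for its group and assumed to vary like the others. Both correlations kept their sign under all alternatives run. The 35 hairpin clusters became 31 at 3 kb and 39 at 50 kb.

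In identical reads 15 called ratios, of all miRNAs kept, no longer had their sign, and the cause was not tested. For 5 the interval excluded equality: miR-19c (-1.13) and miR-9 (0.45) in pooled embryos and miR-93 (-1.36) at 12 dpf for NBH against SC, and miR-301a (-1.95) and miR-27b (-1.86) for stage in SC. For the other 10 it included equality, so that these reads gave no direction: miR-363 (0.0646) in pooled embryos, miR-458 (dre) (0.27), miR-725 (0.73) and miR-129 (0.16) for NBH against SC at 12 dpf, miR-458 (dre) (-1.41), miR-725 (-1.58), miR-142b (tni) (-0.92) and miR-190 (-2.80e-06, equality) for stage in SC, and miR-18c (0.27) and miR-2184 (-0.29) for stage in NBH. The median of the miR-181 list in pooled embryos also turned (-0.50), through miR-181b, which had 18 identical reads in NBH and 270 in SC, while miR-181a stayed higher (2.78). The summed counts of the miR-17-92 clusters gave 0.38 in pooled embryos, against a median of -0.71.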

Other observations

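Of the 100 percentiles of the 25 lists in 4 comparisons, 14 lay below 2.5 or above 97.5, where 5 would be outside if list members behaved like randomly drawn miRNAs. Pairs of one family had closer ratios than random pairs in 3 of the 4 comparisons, which makes extreme medians likelier for lists of related miRNAs. The lists and comparisons are also not independent of each other. The other 18 lists, such as those of muscle, neural, blood, and liver and gut miRNAs, stayed inside in all 4 comparisons. Within the muscle list miR-206 and miR-1 were higher at 12 dpf in SC (3.24 and 1.32) while miR-499 and miR-133c, the latter with 70 counts in the pool and 29 at 12 dpf, were lower (-1.79 each), although identical reads gave no direction for miR-133c. In NBH the ratios of these 4 were 2.13, 0.80, -1.46 and 0.61, the last with an interval that included equality.

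Pairs of one miRNA family had closer ratios than random pairs in 3 of the 4 comparisons. In pooled embryos the ratios of NBH to SC of 120 family pairs differed by a median of 0.48 (95% of random sets of that size gave 0.74 to 1.17), at 12 dpf by 0.79 (0.95 to 1.43) and for stage in SC by 0.79 (1.24 to 1.98). For stage in NBH the 0.74 lay inside the random range of 0.69 to 1.10. Among 48 pairs of entries with a single name and few shared reads the medians were 0.44, 1.07, 0.61 and 0.57 in the same order, and the 1.07 at 12 dpf lay inside the random range of 0.84 to 1.64. The 33 pairs held to come from one primary transcript in other vertebrates differed by 0.82, 0.92, 1.26 and 0.95, inside the random range in all 4 comparisons.

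Of the hairpins, 90 lay on the plus strand, and 87 fell into 35 clusters with gaps of up to 10 kb. The cluster with the most, 6 hairpins, spanned positions 128917 to 129768 of scaffold 545 on the plus strand, and one of 5 spanned 856541 to 857535 of scaffold 9981 on the minus strand. The hairpins carry no names, and the build is not given in the sources used here.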
